A study of Mus musculus with 5 samples.

How the data were processed

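RNA from the left ventricle of C57BL/6 mice was sequenced on an Illumina HiSeq instrument, per the labels. The mice received daily injections for 5 days from an age of 8 weeks, either of citrate buffer (Control, 2 samples) or of streptozotocin at 70 mg/kg (STZ, 3 samples), and were 12 weeks old at sampling, per the labels. The labels number the samples of a group without stating that each is a separate animal, and each was treated here as an independent replicate.

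Reads were handled with CASAVA 1.8.2 and aligned to the mouse genome mm9 with TopHat, per the submitters' processing notes, which give no TopHat version. The 6 deposited tables are comparisons of cassette exons (exons that a transcript either holds or skips) made by the authors with MISO, per the file headers. MISO estimates for each exon the share of transcripts that include it, called Psi, from reads that fit one isoform as well as reads that fit both. Its version, the event annotation and the filter on events are not given in the sources used here. In each of them a single library stands against another, so no library was pooled.

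Psi is deposited by the authors as a fraction between 0 and 1, a posterior mean rounded to 2 decimals, per the file headers. Read counts are deposited by the authors as raw counts in 4 classes for each exon and library, a unit recorded as other, per the file headers: reads that fit only the including isoform, only the skipping isoform, both, or neither. The difference column of the authors' tables, also of the unit other, equals Psi of the first library minus Psi of the second in every line. The Bayes factor is deposited by the authors as a ratio of the evidence for a difference in Psi to that for none, per the file headers, and 8 of its values are infinite. The values of a library were the same in every table that holds it, with 0 differences. The 36 other columns of values per library, which include the bounds of the authors' credible intervals and the reads assigned to each isoform, were not used.

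The tables name the libraries by codes that match no sample title. Of the 5 libraries, 2 stand on one side of every table and 3 on the other, so the 2 were taken as Control and the 3 as STZ from these group sizes alone. They are called Control A, Control B, STZ A, STZ B and STZ C in the order of the number in their codes, since the replicate numbers of the labels cannot be matched to them. The codes also form 2 series of names that split exactly as the groups do.

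The tables held 6616 exons, of which 6331 were in all 6 tables. Genes were named by matching the lengths of the exon and of both introns beside it to a mouse annotation of another build (5895 exons), then by the gene the files give (354), by the length of the skipping junction (86) and by an exon shared with a named event (196), and 86 stayed without a name. Where the files also gave a gene, the length match gave the same Ensembl gene for 97.7% of 3311 exons. Coordinates are those of the files, in mm9, counted from 1 at the first base. The mm9 sequence was not among the sources used here, so no binding motif was searched, and whether an exon is coding was not analysed here.

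An exon was tested where every library had at least 10 informative reads, which are the reads of the including isoform alone plus those of the skipping isoform alone. Psi was clipped to the range from 0.01 to 0.99 and put on the logit scale. STZ was compared with Control in limma 3.58.1, two-sided, with empirical Bayes moderation and a prior variance that follows the log2 mean of informative reads. The p-values were adjusted by the Benjamini-Hochberg method over all tested exons, and exons at an adjusted p under 0.05 are called changed. A second count took the exons whose difference in the authors' tables was at least 0.20 with the same sign and whose Bayes factor was at least 10 in all 6 comparisons. The median change of Psi over all exons was tested by an exact permutation over the 10 splits of the libraries into 2 and 3.

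Gene lists were tested per gene with Fisher's exact test, two-sided, against all other genes with a tested exon. A gene counted when at least 1 of its exons passed a looser rule, an unadjusted limma p under 0.05 with a change of Psi of at least 0.10, and the p-values were adjusted over the 15 lists. The lists were written from general knowledge and share genes with each other. The limma function fry gave a second test of each list: its PValue.Mixed tests change in either direction, and it does not compare a list with other genes. The share of exons whose length is a multiple of 3 was compared by Fisher's exact test between exons past the looser rule and the other tested exons.

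The groups, tests, thresholds, gene lists, the alternatives not said to be added later and the rule for named exons were set before the data were examined. The rule names the 15 exons with the largest rise and the 15 with the largest fall among called exons whose groups do not overlap, up to 4 exons of each list past the looser rule by p, and one exon, with most informative reads, of each of 16 genes chosen for their known place in heart splicing. An item that the rule names is not reported here. Genes or exons named outside that rule are said to have been chosen after their values were seen. Event reads per gene, the sum over a gene's exons of all classes but neither isoform, were compared after the data were seen, as log2 reads per 1000000 event reads with a prior of 0.5 reads, in limma, for genes with at least 200 such reads. Event reads cover the listed exons and their neighbours only and are not gene expression.

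The test was tried on simulated data, with beta-binomial reads at the depths of these libraries and changes of 0.5, 1 or 2 on the logit scale placed in 200 or 600 exons. With 200 changed exons limma called 0%, 5.97% and 19.7% of the 3 sizes, and 29 of its 46 calls were exons without a built-in change, while of its 17 calls of at least 0.10 in Psi 0 were. With 600 changed exons it called 2%, 12% and 36%, and 39 of 139 calls, but 0 of the 99 of at least 0.10, were unchanged exons. Calls of at least 0.10 are given first, since 0 of them were unchanged exons in either simulation. Simulated Psi was the share of inclusion-only reads among informative reads. The deposited Psi is also estimated from reads that fit both isoforms. False changes that arise from those reads could therefore not appear in the simulation, and its shares do not give the error of the real calls. Of the calls under 0.10, 29 of 29 and 39 of 40 were unchanged exons. No change under 0.5 on the logit scale was built in, and none in exons of very low or very high inclusion. These shares therefore do not carry over to real calls under 0.10. The looser rule recovered 26.9%, 64.2% and 84.8% of the 200 changed exons in the 3 sizes, and 27 unchanged exons passed it.

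A quasi-binomial model on the inclusion-only and exclusion-only reads served as an alternative. Its first version recovered none of the simulated changes, so the prior of its dispersion was then taken from exons with at least 10 reads of the rarer class. That change was made on simulated data, and the first version had called fewer exons in the real data. As it stands the model recovered 11.9%, 53.7% and 86.4% of the 200 changed exons, with 3 unchanged exons among 104 calls.

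Other alternatives were no read minimum, minimums of 20 and 50 reads, clipping at 0.001 and at 0.05, untransformed Psi, a constant or robust prior, array weights, other thresholds of the difference and Bayes factor, and each library left out in turn. Leaving out a Control leaves that group with 1 library, which is then assumed to vary like the STZ libraries. Stratification of the list test by tested exons per gene and reads, all alternatives for event reads and marker shares, and the direction of the RNA-binding list among called exons were added after the data were seen. The median of informative reads per tested exon lay between 94 and 192 in the 5 libraries. Reads are not independent molecules, so the error of read counts exceeds counting error alone. Tools were R 4.3.3 with data.table (version 1.17.8) and statmod 1.5.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.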

Results

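Exon inclusion was measured by RNA sequencing in 2 Control and 3 STZ samples of mouse left ventricle. Streptozotocin destroys the insulin-producing beta cells of the pancreas and is used to make mice diabetic. Inclusion is given as Psi, the fraction of a gene's transcripts that hold a cassette exon, as deposited by the authors. Values for 6331 exons were in every table, and 4769 exons of 3235 genes had the reads to be tested. Control A and Control B had 17154734 and 20963751 reads of all 4 classes on these events, and STZ A, STZ B and STZ C had 14913419, 14534868 and 12692236. The reads that tell the isoforms apart came to 3248471 and 4173228 in the Control libraries and to 2997882, 2912232 and 2537025 in the STZ libraries. The median tested exon had 154, 192, 118, 102 and 94 such reads in the same order. Values below are means ± SD, with n = 2 for Control and n = 3 for STZ. Which libraries are Control and which STZ was taken from the group sizes alone, 2 against 3.

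The comparison of STZ with Control asks how transcripts differ in the heart of mice made diabetic, per the labels. The codes of the libraries form 2 series that split exactly as the groups do. Handling or sequencing series and STZ treatment therefore cannot be told apart for any exon below. Many cassette exons differed in Psi, and in more of them Psi was lower in STZ than higher. Whether the lower depth of the STZ libraries adds to these falls of Psi stays open. Of the called exons, 485 changed by at least 0.10 in Psi, 339 towards skipping and 146 towards inclusion, and 285 changed by at least 0.20. Named examples towards inclusion were Lrif1, Rbm7, Eif4a2 and Tra2b, and towards skipping Traf6, Morf4l2, Hnrnph1 and Ptbp1. Genes of RNA-binding and splicing proteins, of cell adhesion and the cytoskeleton, and of 2 lists linked to splicing factors held an exon past a looser rule more often than other genes. Stratified by reads and by tested exons per gene, only the adhesion list did (adjusted p = 0.0029; the others 0.113, 0.0519 and 0.269). With a difference of at least 0.20 and a Bayes factor of at least 10 in all 6 comparisons as the rule, only the RNA-binding list did (adjusted p = 3.44e-05), and the adhesion list did not (0.0958).

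In limma 713 of 4769 exons (15%), in 630 genes, passed an adjusted p of 0.05, 231 with higher and 482 with lower inclusion in STZ. The groups did not overlap in any of the 713, and they did not overlap in 42.9% of all tested exons, where chance gives 20%. Libraries of the same group correlated on the logit scale at 0.967 to 0.977 across exons, and libraries of different groups at 0.927 to 0.935; exons are not independent replicates. The mean absolute difference of Psi was 0.0363 between the Control libraries, 0.0468 to 0.0501 between STZ libraries and 0.0786 to 0.0884 between groups. In the authors' deposited table of each comparison, 204 exons had a difference of at least 0.20 and a Bayes factor of at least 10 in all 6 comparisons, 68 higher and 136 lower in STZ. Of these 192 were tested, and 91.1% of those were called in the same direction. Of the 485 exons above, 401 were also called in the same direction by a model of the reads, and 47 had fewer than 10 reads of the skipping isoform alone. The read share given below is the mean share of inclusion-only among inclusion-only and exclusion-only reads, not corrected for length. It stands beside called exons where its change and that of Psi differ by over 1.5 times. Its level can lie far from Psi at other exons too. The number of called exons was 282 without Control A, 310 without Control B, 467 without STZ A, 304 without STZ B and 348 without STZ C. Calls under 0.10 numbered 228 here. On simulated data 29 of 29 and 39 of 40 such calls were exons without a change. No change under 0.5 on the logit scale was simulated, so these shares do not carry over to the 228 calls.

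**Figure D1:**
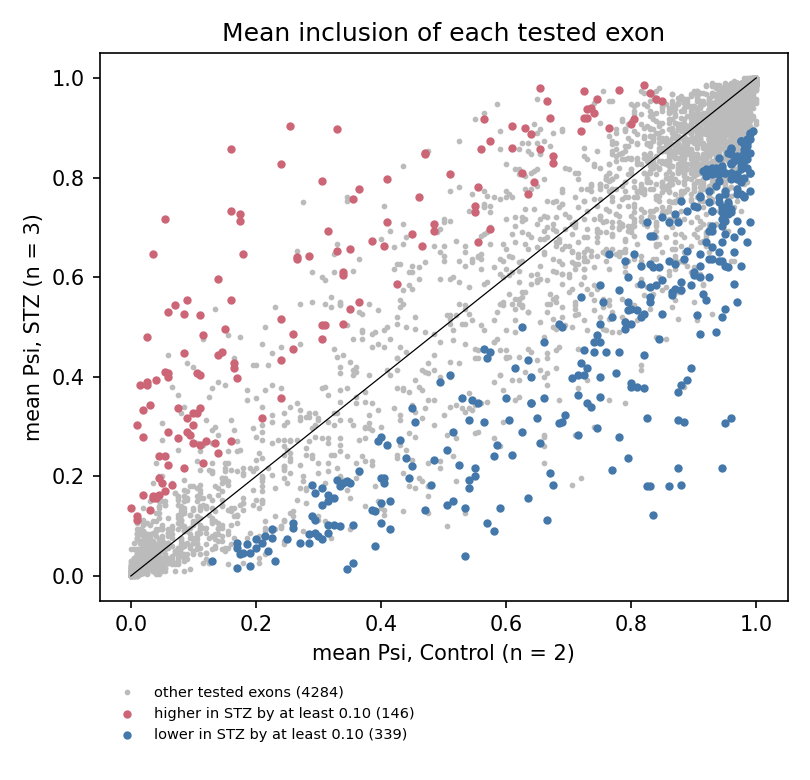
Mean Psi of each of the 4769 tested exons in Control (horizontal axis, n = 2) and STZ (vertical axis, n = 3), as fractions. Red points are the 146 called exons higher in STZ by at least 0.10, blue points the 339 lower by at least 0.10, grey points the other exons, and the line marks equal Psi.

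Among the largest rises of inclusion, a 270-nt exon of Lrif1, which binds nuclear receptors (chromosome 3, 106536255 to 106536524), rose from 0.055 ± 0.0212 to 0.717 ± 0.0603 (adjusted p = 0.0106). In Rbm7, a subunit of a complex that brings RNA to the nuclear exosome, a 105-nt exon (chromosome 9, 48302388 to 48302492) rose from 0.16 ± 0.0283 to 0.733 ± 0.0115 (adjusted p = 0.00395). A 111-nt exon of Eif4a2, an RNA helicase of translation initiation (chromosome 16, 23112424 to 23112534), rose from 0.09 ± 0 to 0.553 ± 0.0321 (adjusted p = 0.00267), with 880 inclusion-only and 3332 exclusion-only reads in Control and 9323 and 2971 in STZ. Exons of the splicing factors Srsf11 (109 nt, 0.255 to 0.903), Tra2b (276 nt, 0.06 to 0.53) and Srsf7 (460 nt, 0.14 to 0.597) also rose. Inclusion rose in the chromatin genes Wiz, a partner of histone methyltransferases (0.175 to 0.713), and Mtf2, a Polycomb protein (202 nt, 0.33 to 0.897; 362 nt, 0.18 to 0.647). The others with the largest rises were exons of Wdcp (0.16 to 0.857), Abhd18 (0.035 to 0.647), Ttc17 (0.24 to 0.827), Rdh13, a retinol dehydrogenase (0.175 to 0.727), Gprasp1 (0.305 to 0.793) and Picalm, a clathrin assembly protein (150 nt, 0.07 to 0.543). The read share rose by less than Psi at exons of Srsf11 (0.777 to 0.993), Srsf7 (0.799 to 0.978), Ttc17 (0.616 to 0.974), Gprasp1 (0.61 to 0.925) and the 202-nt exon of Mtf2 (0.862 to 1). Adjusted p-values of these 15 exons ran up to 0.0294 in limma. Leaving out any 1 of the 5 libraries ended the calls of Wdcp (adjusted p = 0.0526 to 0.08) and Rdh13 (0.053 to 0.128). Leaving out Control A, Control B or STZ B ended those of Srsf7 (up to 0.119), the 362-nt exon of Mtf2 (0.0844), Tra2b (0.084), Picalm (0.0981) and Abhd18 (0.0771). Leaving out STZ C ended those of Srsf7 and that exon of Mtf2 too, and leaving out Control A that of Srsf11 (0.0548).

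Among the largest falls of inclusion, a 203-nt exon of Traf6, a ubiquitin ligase of innate immune signalling (chromosome 2, 101520982 to 101521184), fell from 0.835 ± 0.106 to 0.123 ± 0.0503 (adjusted p = 0.0291), with 169 inclusion-only and 15 exclusion-only reads in Control and 36 and 151 in STZ. In Morf4l2, a subunit of a histone acetyltransferase complex, a 77-nt exon (chromosome X, 133270085 to 133270161) fell from 0.96 ± 0.0141 to 0.317 ± 0.0351 (adjusted p = 0.00614), and so did its overlapping annotations of 76 and 75 nt. A 139-nt exon of Hnrnph1, a splicing regulator (chromosome 11, 50194961 to 50195099), fell from 0.875 ± 0.0354 to 0.313 ± 0.0252 (adjusted p = 0.00759), with its overlapping annotation of 92 nt. The read share of the 139-nt and 92-nt exons fell less, from 0.986 to 0.81 and from 0.966 to 0.663. A 176-nt exon of Mettl3, the catalytic subunit of the m6A RNA methyltransferase, fell from 0.885 ± 0.0354 to 0.31 ± 0.0436 (adjusted p = 0.0107; read share 0.941 to 0.566). Inclusion fell in Dpp7, a lysosomal peptidase (0.945 to 0.217; read share 1 to 0.541), Huwe1, a ubiquitin ligase (234 nt, 0.875 to 0.217; read share 0.977 to 0.576), Pml, the scaffold of nuclear bodies (0.665 to 0.113), Zfp266 (0.86 to 0.18; read share 0.996 to 0.757), Fam171a1 (0.77 to 0.213) and Hmgxb4 (0.825 to 0.317). Psi also fell at a 66-nt exon of Mettl3 (0.95 to 0.307) and a 120-nt exon of Arvcf, a catenin (0.88 to 0.183). Reads of the skipping isoform alone were 0 in every library for that exon of Mettl3, and 5 in Control and 1 in STZ for that of Arvcf, so there the fall of Psi came with no rise of skipping reads and was not called by the read model (adjusted p = 1 and 0.503). Leaving out any 1 of the 5 libraries ended the calls of Traf6 (adjusted p = 0.0719 to 0.105) and Zfp266 (0.0581 to 0.138). Leaving out any but STZ C ended those of Huwe1 (0.0539 to 0.114), Pml (0.0583 to 0.131) and Hmgxb4 (0.0691 to 0.14). The call was lost for Fam171a1 without Control A, Control B or STZ C (up to 0.0812), for Arvcf without Control A or Control B (0.0543) and for Dpp7 without Control B or STZ B (0.0537).

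**Figure D2:**
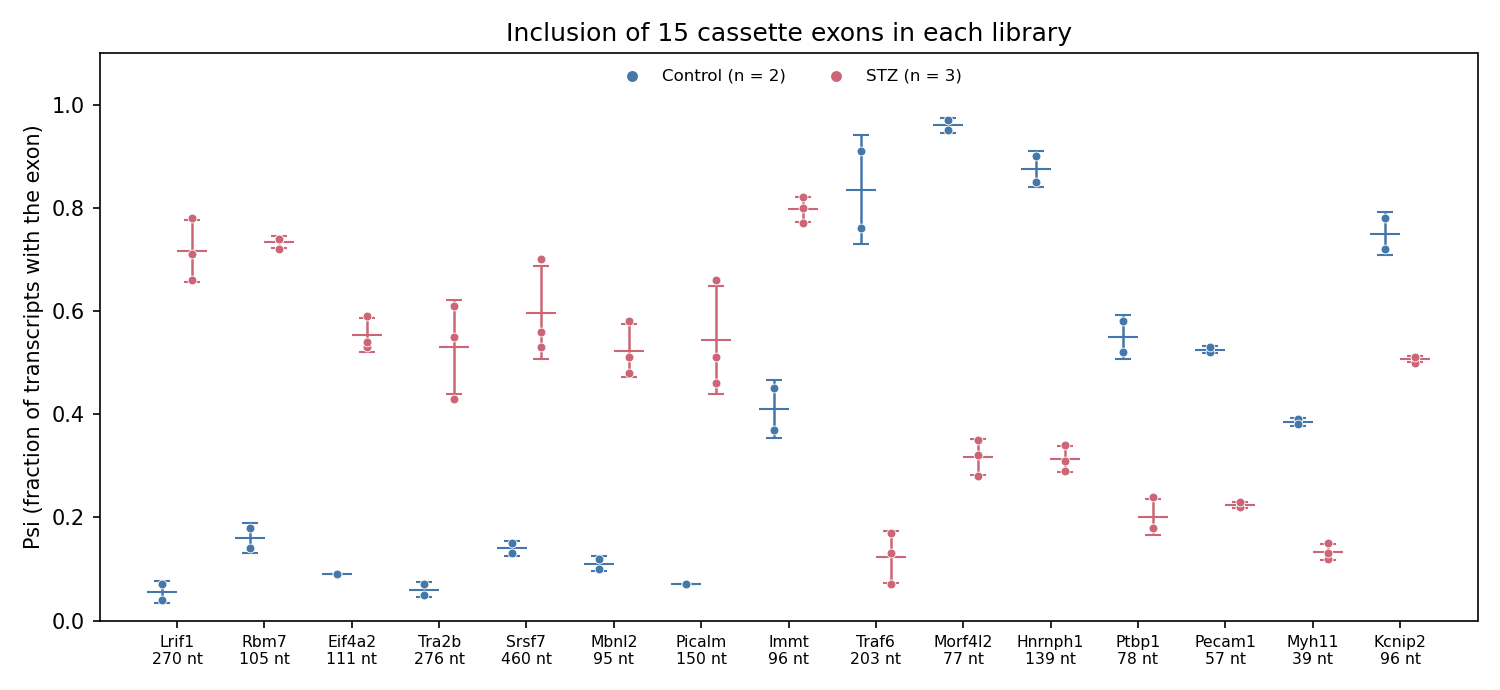
Psi of 15 named cassette exons, as a fraction (vertical axis), in each Control library (blue, n = 2) and STZ library (red, n = 3). Points are libraries, long bars means and error bars SD; the groups do not overlap at any of the 15 exons.

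Of 16 genes chosen beforehand for their place in heart splicing, 12 had a tested exon, while Rbfox1, Insr, Tpm1 and Cacna1c had none. Among the exons with most reads, a 78-nt exon of Ptbp1, a splicing repressor, fell from 0.55 ± 0.0424 to 0.2 ± 0.0346 (adjusted p = 0.018), and a 95-nt exon of Mbnl2, a splicing regulator, rose from 0.11 ± 0.0141 to 0.523 ± 0.0513 (adjusted p = 0.00926). A 152-nt exon of Celf1, a regulator of heart splicing in development, fell from 0.315 ± 0.00707 to 0.227 ± 0.00577 (adjusted p = 0.0135), a change under 0.10. Nearly all simulated calls that small were of unchanged exons, but no change under 0.5 on the logit scale was simulated. For Rbfox2, a splicing regulator of heart muscle, a 43-nt exon had a Psi of 0.9 ± 0.0424 in Control and 0.81 ± 0.106 in STZ (adjusted p = 0.435). A 24-nt exon of the transcription factor Mef2a was at 0.785 ± 0.0636 and 0.557 ± 0.125 (adjusted p = 0.179), and a 186-nt exon of the Z-disc gene Ldb3 at 0.77 ± 0.0849 and 0.953 ± 0.0153 (adjusted p = 0.0513). The exons with most reads of Camk2d (0.79 and 0.79), Tnnt2 (0.68 and 0.72), Fn1 (0.975 and 0.947), Celf2 (0.905 and 0.83), Mbnl1 (0.98 and 0.97) and Ttn (0.995 and 0.99) did not pass either. The call was lost for Ptbp1 without any 1 library but STZ A (adjusted p = 0.0669 to 0.0897), for Celf1 without Control A or Control B (0.0532 to 0.0651) and in the read model (0.0506), and for Mbnl2 without Control A (0.057). The read model called the exons of Mef2a (adjusted p = 0.000954), Ldb3 (0.00155) and Tnnt2 (0.0149). The read share of the Ldb3 exon moved far less than Psi, from 0.978 in Control to 0.997 in STZ. That exon of Ldb3 passed in limma too with Psi clipped at 0.001 (0.0443) or at 0.05 (0.05) and with array weights (0.0469).

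RNA-binding and splicing proteins held an exon past the looser rule (unadjusted p under 0.05 and a change of at least 0.10) in 25 of 61 tested genes. Besides the exons of Srsf11, Srsf7, Tra2b, Hnrnph1, Ptbp1 and Mbnl2, inclusion fell at a 141-nt exon of Hnrnpab from 0.515 ± 0.0212 to 0.29 ± 0.01 (adjusted p = 0.0066). Among its exons past the looser rule 25 were higher and 15 lower in STZ. The share of genes, 41%, was above the 23.2% of all genes (odds ratio 2.34, 95% confidence interval 1.33 to 4.03; Fisher's exact test, adjusted p = 0.0121). Of the 117 exons of the list 19 rose and 22 fell when adjusted over all exons, and 54 were called when adjusted over the list alone. Stratified by reads and by tested exons per gene, a test added after the data were seen, the adjusted p was 0.113.

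Adhesion, matrix and cytoskeleton genes had the highest share of all lists of at least 10 genes, with an exon past the looser rule in 23 of 42 genes (54.8%). A 279-nt exon of Add1, an adducin that caps actin filaments, rose from 0.105 ± 0.00707 to 0.407 ± 0.0208 (adjusted p = 0.00395). A 105-nt exon of Clip1, a microtubule plus-end protein, rose from 0.095 ± 0.00707 to 0.283 ± 0.00577 (adjusted p = 0.00395). Its read share lay far above Psi, at 0.708 in Control and 0.863 in STZ. Inclusion fell at a 66-nt exon of Mprip, which binds myosin phosphatase, from 0.96 ± 0 to 0.827 ± 0.0115 (adjusted p = 0.00267), and at a 39-nt exon of Myh11, the smooth muscle myosin heavy chain, from 0.385 ± 0.00707 to 0.133 ± 0.0153 (adjusted p = 0.00856). The odds ratio was 4.09 (2.12 to 7.99; Fisher's exact test, adjusted p = 0.000132), and 0.0029 after stratification. Among its exons past the looser rule 9 were higher and 20 lower in STZ. Of its 92 exons 10 rose and 12 fell when adjusted over all exons, and 29 were called when adjusted over the list alone. The list missed the threshold without Control B (14 of 42 genes, adjusted p = 0.0787) and under the rule in all 6 comparisons (6 of 42 genes, adjusted p = 0.0958). The call of Myh11 was lost without Control A and without Control B (adjusted p = 0.0514 to 0.0566).

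Genes linked to the splicing factors MBNL and CELF held an exon past the looser rule in 16 of 34 cases (47.1%), and genes linked to RBFOX in 19 of 43 (44.2%). A 72-nt exon of Ktn1, a kinesin-binding membrane protein on both lists, rose from 0.665 ± 0.0212 to 0.953 ± 0.00577 (adjusted p = 0.00398; read share 0.813 to 0.982). Inclusion rose at a 54-nt exon of Mbnl1 from 0.1 ± 0 to 0.267 ± 0.0306 (adjusted p = 0.0147) and fell at a 119-nt exon of Cers2, a ceramide synthase, from 0.98 ± 0 to 0.84 ± 0.0346 (adjusted p = 0.0107; read share 0.997 to 0.914). A 114-nt exon of Rapgef1, an exchange factor for Rap, fell from 0.43 ± 0.0141 to 0.273 ± 0.0153 (adjusted p = 0.0134). The odds ratios were 2.98 (1.41 to 6.22) and 2.65 (1.37 to 5.09), each with an adjusted p of 0.0121 in Fisher's exact test, and the stratified adjusted p was 0.0519 and 0.269. Past the looser rule 8 exons of the MBNL and CELF list were higher and 13 lower, and 12 and 17 of the RBFOX list. Of the 70 MBNL and CELF exons 6 rose and 13 fell, and of the 108 RBFOX exons 9 rose and 13 fell, with 21 and 32 called when adjusted over the list alone. Of the tested genes 25 of 34 and 34 of 43 are also on another list, and the lists, written from general knowledge, may hold genes first linked to these factors in hearts like these. The MBNL and CELF list missed the threshold without Control B (12 of 34 genes, adjusted p = 0.0836) and with at least 20 informative reads (13 of 32 genes, adjusted p = 0.0927). Under the rule in all 6 comparisons neither that list (5 of 34 genes, adjusted p = 0.0976) nor the RBFOX list (6 of 43, 0.0958) passed, and without Control A or Control B the calls of Mbnl1 (up to 0.0821), Cers2 (0.0675) and Rapgef1 (0.0729) were lost, those of Mbnl1 and Rapgef1 without STZ C too.

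**Figure D3:**
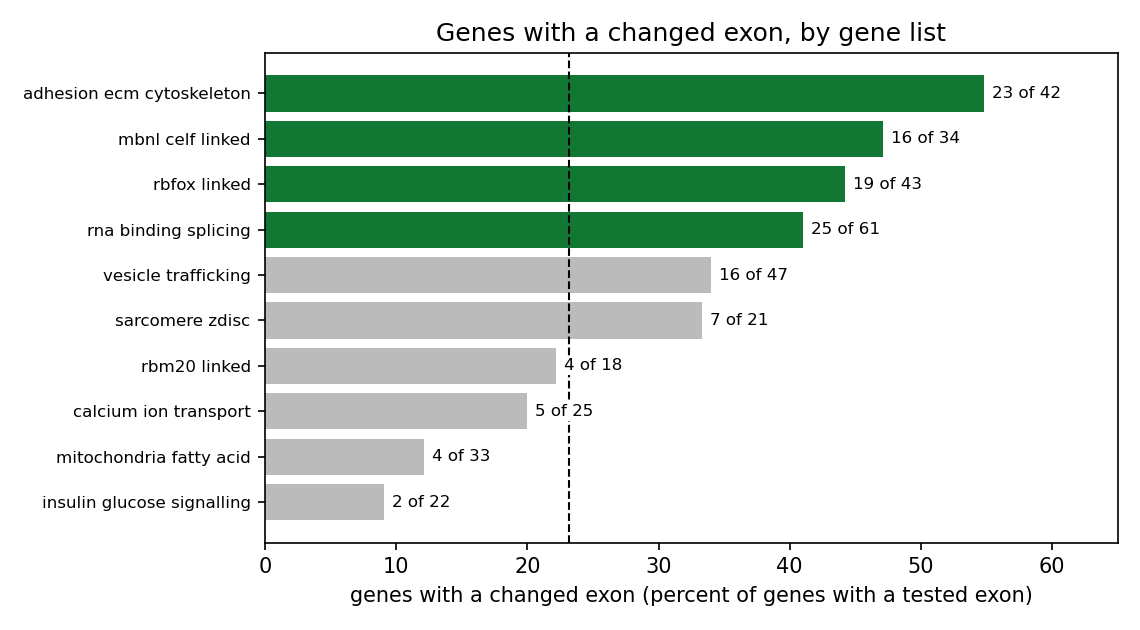
Percent of genes with a tested exon that hold an exon past the looser rule, for the 10 gene lists that are not cell type markers, with the number of genes beside each bar. Green bars are the 4 lists past the threshold in Fisher's exact test, and the dashed line marks 23.2%, the share of all genes.

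Sarcomere and Z-disc genes had an exon past the looser rule in 7 of 21 cases (adjusted p = 0.55), calcium and ion transport genes in 5 of 25 (1), and genes linked to RBM20, a regulator of titin splicing, in 4 of 18 (1), all by Fisher's exact test. In these groups inclusion fell at exons of Obsl1, an obscurin-like protein (0.315 to 0.15; read share 0.586 to 0.326), Ablim1 (105 nt, 0.22 to 0.05; 0.61 to 0.228), Kcnip2, a subunit of transient outward potassium channels (96 nt, 0.75 to 0.507; 0.902 to 0.771), and Ttn, the giant spring protein (138 nt, 0.86 to 0.633; 0.98 to 0.925). Psi rose at a 675-nt exon of Palld, an actin-bundling protein (0.725 to 0.973), which had 4 exclusion-only reads in Control and 1 in STZ, with a read share of 0.999 and 1. Exons of Ank3 (0.04 and 0.163), Atp2b1, a calcium pump (0.34 and 0.193), Slc4a4, a bicarbonate transporter (0.585 and 0.947), and a 2646-nt exon of Ttn (0.91 and 0.7) did not pass the adjusted threshold. The number of exons called when adjusted over the list alone was 9 for the sarcomere list, 4 for ion transport and 7 for RBM20. The call was lost for the 138-nt exon of Ttn without any 1 of the 5 libraries (adjusted p = 0.0658 to 0.121), with Psi clipped at 0.05 (0.059) and with robust empirical Bayes (0.0501). It was lost for Palld without any but STZ A (0.0646 to 0.095) and in the read model (0.79), and for Kcnip2 without any 1 STZ library (0.0623 to 0.0714). Without Control A or Control B it was lost for Obsl1 (up to 0.054) and Ablim1 (0.0796), and without STZ B for Ablim1 too. The read model called the exons of Atp2b1 (adjusted p = 0.000433) and Slc4a4 (0.000179). The read share of the Slc4a4 exon moved less than Psi, from 0.852 in Control to 0.998 in STZ. In limma that exon of Slc4a4 also passed with untransformed Psi (0.0189) and without STZ C (0.0342).

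Genes of mitochondria and fatty acid use had an exon past the looser rule in 4 of 33 cases (adjusted p = 0.321), insulin and glucose signalling genes in 2 of 22 (0.321) and vesicle trafficking genes in 16 of 47 (0.249), all by Fisher's exact test. With a difference of 0.05 in place of 0.10 the trafficking list passed, with 27 of 47 genes (odds ratio 3.16, adjusted p = 0.000756). A 39-nt exon of Dnm1l, the GTPase of mitochondrial fission, rose from 0.04 ± 0.0141 to 0.393 ± 0.107 (adjusted p = 0.0261). A 96-nt exon of Immt, which shapes mitochondrial cristae, rose from 0.41 ± 0.0566 to 0.797 ± 0.0252 (adjusted p = 0.0145; read share 0.638 to 0.874), as did its 90-nt overlapping annotation. A 140-nt exon named Acsl3, an acyl-CoA synthetase, by the length match fell from 0.515 ± 0.0778 to 0.15 ± 0.02 (adjusted p = 0.0191). The authors' annotation gives another gene, Utp14b, for this exon, so its place on the list is uncertain. It had a mean of 26 informative reads and a minimum of 11. On the insulin list an exon of Gfpt1 was at 0.935 and 0.78 (adjusted p = 0.142). Among trafficking genes Psi fell in Agfg1 (0.93 to 0.693), Eps15 (0.86 to 0.71) and Tom1 (0.94 to 0.76). Their read share moved less, from 0.984 to 0.915, from 0.956 to 0.878 and from 0.992 to 0.974, and the read model did not call Tom1 (adjusted p = 0.102). Exons called when adjusted over the list alone numbered 10 for mitochondria, 1 for insulin and 20 for trafficking. The call was lost for Dnm1l without any 1 of the 5 libraries (adjusted p = 0.0573 to 0.119) or with untransformed Psi (0.0606). It was lost for Acsl3 without any but Control A (0.053 to 0.0747), for the 90-nt exon of Immt without any but STZ A (0.0697 to 0.103) and for its 96-nt exon without Control A, STZ B or STZ C (0.0533 to 0.0619). It was lost for Agfg1 (0.0792 to 0.0922) and Tom1 (0.052 to 0.0553) without any 1 STZ library, and for Eps15 without Control B or STZ C (0.0538 to 0.0547).

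Markers of cell types were too few on the tables for a strong test of their lists. In the endothelial list 2 of 5 genes had an exon past the looser rule (adjusted p = 0.55), in the smooth muscle list 1 of 6 (1), in the blood and immune list 1 of 3 (0.79), in the cardiomyocyte list 1 of 4 (1) and in the fibroblast list 0 of 4 (0.79), by Fisher's exact test, with 3, 2, 0, 1 and 1 exons called when adjusted over the list alone. A 57-nt exon of Pecam1, an adhesion molecule of endothelial cells (chromosome 11, 106533056 to 106533112), fell from 0.525 ± 0.00707 to 0.223 ± 0.00577 (adjusted p = 0.00118). A 65-nt exon of Egfl7, secreted by endothelial cells, fell from 0.95 ± 0.0283 to 0.687 ± 0.0231 (adjusted p = 0.0285; 0.0862 to 0.102 without any 1 STZ library), with a read share of 0.982 and 0.864. An exon of Itgb2, a leukocyte integrin, was at 0.93 ± 0.0283 and 0.807 ± 0.0577 (adjusted p = 0.103). Event reads here are those that fit either or both isoforms. Endothelial markers took 0.212% ± 0.0171 of event reads in Control and 0.612% ± 0.155 in STZ, and without Pecam1 0.0293% ± 0.00264 and 0.0393% ± 0.0129. In a comparison of event reads per gene chosen after the data were seen, Pecam1 rose (log2 change 1.62, adjusted p = 0.000499), and so did Mmrn2 (0.91, 0.035), which lost the call in leave-one-out fits (up to 0.132). Robo4 (0.70, adjusted p = 0.0738; 0.0417 after centring on the median), Egfl7 (-0.29, 0.351) and Emcn (-0.01, 0.973) did not pass. Smooth muscle markers, beside the fall at Myh11, took 10.3% ± 0.016 and 3.49% ± 0.511, and without Pln, which heart muscle also expresses, 0.0755% ± 0.00427 and 0.108% ± 0.0257. Cardiomyocyte markers took 14.3% ± 0.131 and 7.73% ± 0.642, and without Pln 4.06% ± 0.111 and 4.35% ± 0.292. Fibroblast markers took 0.0951% ± 0.0132 and 0.148% ± 0.0372, and blood and immune markers 0.0125% ± 0.00106 and 0.0191% ± 0.00696. With reads of neither isoform counted too, the shares turned for smooth muscle markers without Pln (0.319% and 0.142%), cardiomyocyte markers without Pln (5.35% and 5.17%) and endothelial markers without Pecam1 (0.0587% and 0.0551%). In fry, PValue.Mixed, which tests change in either direction and does not compare a list with other genes, was at most 0.00576 for every list except blood and immune markers (0.0891).

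Exons whose length is a multiple of 3, which leave the reading frame of a coding exon intact when skipped, made up 479 of 894 exons past the looser rule (53.6%) and 1699 of 3875 other exons (43.8%). The odds ratio was 1.48 (95% confidence interval 1.27 to 1.72; Fisher's exact test, two-sided, p = 1.76e-07). The test was not stratified by inclusion or reads. Of the 1836 exons with a mean Psi of 0.9 to 1, 7.9% were called, against 32.6% between 0.3 and 0.5 and 24% between 0.5 and 0.7. The odds ratio may thus reflect which exons can change. Overlapping annotations count as separate exons, so the p-value and interval may be too narrow. Examples past the rule are the exons of Lrif1, Pecam1 and Ktn1 and the 111-nt exon of Eif4a2. The overlapping Eif4a2 annotation of 107 nt has a length that is not a multiple of 3. Its mean Psi rose too, from 0.06 in Control to 0.407 in STZ. The median change was lowest for exons of middle inclusion, -0.0617 for exons with a mean Psi between 0.3 and 0.5, -0.075 between 0.5 and 0.7 and -0.06 between 0.7 and 0.9. Over all tested exons the median change was -0.01, with quartiles of -0.0617 and 0.01 (exact permutation test, two-sided, p = 0.1). That is the smallest p that 10 splits can give.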

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

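The tests of the fall in inclusion and of other splits of the libraries were chosen after the results were seen. Reads on the events that fit neither isoform, which no test of the report uses, took a higher share in STZ than in Control, 47.7% ± 1.21 (SD, n = 3) against 45.8% ± 0.506 (SD, n = 2). By library the share was 46.2% in Control A and 45.5% in Control B, and 49.1%, 47.2% and 46.9% in STZ A, STZ B and STZ C.

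The first pattern weighed is that more called exons fell than rose in STZ, Traf6, Morf4l2 and Hnrnph1 among them (482 against 231). The lower depth of the STZ libraries is argued against for the read model alone. With informative reads thinned to those of the shallowest library at each exon, 63.5% of its 820 calls fell (95% confidence interval 60.1 to 66.8), against 64.8% at full depth. Psi was not estimated again at equal depth, so for the calls made on Psi lower depth stays open. Median Psi of the tested exons followed depth: 0.88 in Control B, 0.86 in Control A, and 0.82, 0.81 and 0.8 in STZ A, STZ B and STZ C. Inclusion-only reads made up 86.2% and 87.1% of all informative reads in Control A and Control B. In STZ A, STZ B and STZ C that share was higher, at 87.5%, 88.2% and 87.9%. More reads on the flanking exons without more skipping was weighed by exclusion-only reads per read of both isoforms. Psi is estimated from these same reads, so choosing exons whose Psi fell in itself favours a rise, and the values cannot decide. In the 288 falling calls with at least 10 exclusion-only reads in Control the median log2 change was 0.75 (quartiles 0.22 and 1.60), and 242 were higher. In the 194 with fewer such reads in Control, Dpp7 and Cers2 among them, that change lay a median of 1.47 above exons not called with as few (156 above, 80.4%, 95% confidence interval 74.1 to 85.8). The exons not called were not chosen for a fall. Most falls of Psi thus came with more skipping reads per read of both isoforms, which leaves their cause open. For the 86 of the 194 with fewer than 10 over all libraries, the 66-nt exon of Mettl3 and the exon of Arvcf among them, skipping reads are too few to tell. An effect of streptozotocin treatment on exon skipping may remain for the others, as a hypothesis that these data cannot separate from these explanations or from other differences between the groups.

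Splits of the 5 libraries into 2 and 3 were compared with the real one. The real split gave 713 called exons and the highest of the others 13, so 1 of 10 splits, the real one, gave as many. Every other split mixes Control and STZ libraries within a group. Any difference between Control and STZ, whatever its cause, then adds to the spread within groups and lowers the number of calls. The comparison therefore says nothing of the cause. The 10 splits are too few for a share under 0.05.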

How the results depend on the processing

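Stratification of the list test, reads of neither isoform in marker shares, the direction of the RNA-binding list among called exons and all alternatives for event reads were chosen after the data were seen. The 713 called exons became 282 to 467 when 1 library was left out, where fewer libraries are tested, and lay between 482 and 1033 under the other alternatives. Most called exons fell in each of them. The 204 exons past the rule in all 6 comparisons of the authors' deposited tables became 333 without a Bayes factor, 356 at a difference of 0.10 and 100 at 0.30, as looser and stricter rules do, and 240 to 296 without 1 library. The 4 gene lists past the threshold became 2 without Control B, were 4 in each of the other leave-one-out fits, became 5 at a difference of 0.05 (vesicle trafficking genes added) and 1 under the rule in all 6 comparisons (RNA-binding and splicing genes, adjusted p = 3.44e-05), and 1 after stratification (adhesion genes). The cause was not tested. The odds ratio of frame-preserving exons was 1.35 to 1.54 and passed under each alternative run. The odds ratio for the direction of the RNA-binding list was 4.02 under the looser rule and 1.87 among called exons, where it did not pass (Fisher's exact test, p = 0.0585). The median change stayed negative, between -0.0133 and -0.00667. With reads of neither isoform counted, STZ minus Control of marker shares, in percent of event reads, turned from 0.0328 to -0.176 for smooth muscle without Pln, from 0.29 to -0.172 for cardiomyocytes without Pln and from 0.01 to -0.00364 for endothelium without Pecam1. The 1779 genes whose event reads differed became 973 without Control A and 974 without Control B, and up to 2197 in the other leave-one-out fits. Of 1048 values of named exons under alternatives, 908 kept direction and side of the threshold, 129 lost the call, 10 gained it and 1 reversed: the inclusion share of Arvcf in the read model was 0.0107 higher in STZ (adjusted p = 0.503), where exclusion-only reads are few.

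Of the 57 named exons that were called, 20 were called in every leave-one-out fit and 37 lost the call in at least 1, with a highest adjusted p of 0.14. The call was lost for 30 without Control A, 30 without Control B, 14 without STZ A, 25 without STZ B and 22 without STZ C. The read model also called 514 of the 713 exons in the same direction, and 401 of the 485 with a change of at least 0.10. The inclusion share moved the other way in 9 of the 713 and did not move in 48. Depth limits the 110 called exons with fewer than 10 exclusion-only reads over all libraries. No paired analysis was possible because nothing in the labels pairs a Control with an STZ sample and the libraries match no replicate number.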

Other observations

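Event reads, the genes named from them, the direction of the RNA-binding list and the tests of Pln and of library series were chosen after the values were seen; the tests of that direction by reading frame and by reads were set before their values were known. No group of genes was tested here. Sphk1, which makes sphingosine 1-phosphate, rose from 10.1 ± 0.543 (SD, n = 2) to 325 ± 52.5 (SD, n = 3) reads per 1000000 event reads, a log2 change of 4.99. Ddit3, a stress-induced transcription factor (log2 change 2.80), Tnfrsf10b, a death receptor (4.25), and Ifrd1 (3.64) rose, as did Pfkfb3, a regulator of glycolysis (3.43), Pnpla2, the lipase of stored triglyceride (2.13), and Gpx3, a peroxidase (2.11). Reads fell for Acta1, skeletal actin (-3.34), Ppargc1b, a coactivator of mitochondrial genes (-3.77), Ogn, a matrix proteoglycan (-3.12), Camk2a (-2.69) and Pln, the inhibitor of the calcium pump SERCA (-1.61). The median log2 change over all genes was -0.16, and each gene named here passed an adjusted p of 0.05 in limma and in every leave-one-out fit it was tested in. Event reads cover the listed exons and their neighbours alone and are not gene expression.

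Among genes of the circadian clock, event reads of Arntl rose (log2 change 2.45) and those of Dbp fell (-3.27), while Nr1d1 (-0.05), Tef (-0.05), Hlf (-0.20) and Ciart (0.36) did not pass. Arntl had only 28 event reads in Control A and 14 in Control B, and its log2 change ran from 1.811 to 3.095 in leave-one-out fits. Event reads of Pecam1 rose (1.62) and those of Vegfa, an angiogenic factor, fell (-0.68). The call of Vegfa missed the threshold in at least 1 leave-one-out fit (highest adjusted p = 0.0908).

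The second pattern weighed is that the exons past the looser rule in RNA-binding and splicing genes, such as Srsf7, Tra2b and Srsf11, were higher in STZ more often than others, 25 of 40 (62.5%) against 250 of 854 (29.3%; odds ratio 4.02, 95% confidence interval 2.00 to 8.35, Fisher's exact test, p = 2.77e-05). It depends on that rule: among called exons 19 of 41 in the list rose (46.3%) against 212 of 672 others (31.5%; odds ratio 1.87, 0.936 to 3.71, Fisher's exact test, p = 0.0585). Weaker decay of frame-shifting transcripts in all genes was predicted to raise such exons outside the list too, by odds of at least 2. There the odds ratio of a rise was 1.23 among exons of low inclusion (0.768 to 1.98), with an upper bound only just under 2. Whether an exon is coding was not analysed, and length alone does not tell which transcripts decay. Overlapping annotations are also not independent, so this odds ratio cannot decide. Higher reads of the list are argued against, since the odds ratio stratified by reads was 4.27 (2.11 to 8.96). The 40 changed exons of the list lie in 25 genes, 17 of them with a rising exon. Overlapping annotations count as separate exons in each of these tests of direction, so their p-values and intervals may be too narrow. A change in how these genes control their own splicing may remain as a hypothesis, and it was not tested.

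The third pattern weighed is that event reads of 1779 of 3492 genes differed, 698 higher and 1081 lower in STZ. Reads taken by Pln alone are argued against, since 1830 genes passed without it. The median log2 change was -0.16 with Pln and -0.26 without it, and after centring on the median 956 genes were higher and 868 lower. Without Control A 973 genes passed, and without Control B 974. The names of the libraries form 2 series and 0 groups hold libraries of both, so handling or sequencing series and STZ treatment cannot be told apart.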
